A study of Homo sapiens with 12 samples.

How the data were processed

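RNA was sequenced from T47D-MTVL cells, a derivative of the hormone-responsive breast cancer line T47D with an integrated luciferase reporter under the MMTV promoter. The medium held charcoal-treated serum, per the labels' protocols, and none of the 12 libraries came from cells given the progestin R5020, per the labels. Samples were grouped by their titles into 6 groups of 2 libraries. Poly(A) RNA was measured after transfection of a control siRNA (siCtrl) or a PADI2 siRNA (siPADI2), and in cells labelled as expressing an HA-tagged, alpha-amanitin-resistant RNA polymerase II (RNAP2), either wild type (WT) or the R1810A form. Both RNAP2 groups had 24 hours of expression followed by 12 hours in 6 µg/ml alpha-amanitin, per the labels' protocols. Alpha-amanitin is a toxin that blocks the cells' own RNAP2. Chromatin-associated RNA was measured after siCtrl and siPADI2. This fraction was the pellet left after nuclei were extracted with urea and detergent, treated with DNase and proteinase K, per the labels' protocols. Poly(A) libraries were made with the TruSeq Stranded mRNA kit and chromatin libraries with the TruSeq Stranded Total RNA kit with Ribo-Zero, per the labels' protocols.

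The deposited values are raw counts of fragments per gene, 1 table per library, not normalized. Reads were trimmed with Trimmomatic, aligned with STAR and counted with featureCounts, per the submitters' processing notes. Per the file headers, the authors counted STAR alignments with featureCounts 1.5.1 for poly(A) RNA and 1.4.6-p2 for chromatin RNA, with read pairs counted as fragments, strand option 2, counts summed by gene identifier and GENCODE 19 genes on hg19. The commands set no option to count multi-mapping reads or reads that overlap several genes, per the file headers, so genes with near-identical copies (histones, ribosomal proteins, small nuclear RNAs) have incomplete counts and are reported as uncertain. The strand option separates most antisense genes. Per the file headers no feature type other than the tool's default was set, which is the exon, so reads that lie within introns do not enter the chromatin values. Each table lists 57820 genes.

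Gene symbols and biotypes were matched by stable gene identifier to GENCODE 29, with 52338 of the 57820 genes matched. GC content (52337 genes) and 3′ UTR sequences (18696 genes) came from the transcripts of that release. All coordinates are those of the deposited tables (hg19). The GRCh38 coordinates of GENCODE 29 were not used.

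Total counts, in units of 1e6, ranged from 44.32 to 132.76 in the poly(A) libraries and from 2.72 to 7.04 in the chromatin libraries. The chromatin values of genes with few reads are therefore the least precise. Over genes with a mean count of at least 10, the chi-square statistic per degree of freedom between the 2 libraries of a group ran from 3.55 to 91.7, so no pair agreed within sampling noise and no library was counted as a duplicate. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

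Each comparison was fitted on its own 4 libraries with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are counts per 1e6 of the TMM-scaled library size (CPM), given as mean ± SD over 2 libraries. Differences between effects (siPADI2 against R1810A in poly(A) RNA, and chromatin against poly(A) RNA for siPADI2) were tested as interaction contrasts in joint fits of 8 libraries each. Overlaps of calls were tested with Fisher's exact test (two-sided) against the number that independent lists would share. The compared pairs share no libraries.

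The 24 gene lists, the splits by expression and by gene span, and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. With 4 libraries per fit the estimated correlation and its test rest on few residual degrees of freedom. None of the 24 lists passed with it in any comparison. Not passing with an estimated correlation therefore says little against a list. The estimates lay far above 0.01 for some lists, such as 0.435 for G1/S genes and 0.992 for mitochondrially encoded mRNAs in the R1810A comparison. For others they lay below it, such as −0.0116 for estrogen response genes after siPADI2 in poly(A) RNA. They are too coarse to replace the preset value. Where members of a list vary together, camera p-values at 0.01 are too small. Camera asks whether a list changed more than the other genes, fry whether its members changed at all. With 56.7% of genes called after siPADI2 in poly(A) RNA, passing fry alone says little about a list. A list needed at least 3 measured members to be tested. Of the symbols listed, 31 of 32 G1/S genes, 16 of 26 histone genes, 22 of 25 small nuclear RNAs (snRNAs) and independently transcribed small nucleolar RNAs (snoRNAs), 18 of 19 basal, mesenchymal and immune markers and 4 of 5 peptidylarginine deiminases were matched, and every symbol of the other lists. For the expression split, genes were ranked by libraries outside the comparison (WT for siPADI2 in poly(A) RNA, siCtrl poly(A) for the other comparisons) and camera was run on the highest and lowest 10th. The span split used the distance from first start to last end of a gene.

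Genes were named by a fixed rule. In each comparison these were the 8 higher and the 8 lower protein-coding genes with the largest fold change among those past the threshold, at an average log2 CPM of at least 3 and with both libraries of a group above both of the other. In each difference of effects the 4 with the smallest p in each direction were named, and in each list up to 3 members with the smallest p. PADI2, POLR2A, MYC, CCND1, ESR1, PGR, SERPINA6 and STMN1 were always named.

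The gene test was tested on simulated counts drawn from the real means, depths and dispersions. The changed genes, 66 or 67 per fold, were taken only from genes above a set mean count. The shares below therefore do not hold for genes with few reads, nor where a large part of all genes changes. At 2-fold it recovered 94.0% of changed genes for siPADI2 in poly(A) RNA, 86.6% for R1810A and 59.7% for chromatin RNA, and at 4-fold 100%, 95.5% and 97.0%. Calls on unchanged genes numbered 27, 48 and 8 in these comparisons. Changes of 1.5-fold were recovered at 74.6%, 64.2% and 4.48%. For the difference between the poly(A) comparisons the shares were 49.3%, 79.1% and 95.5% at 1.5-, 2- and 4-fold, and for the difference between chromatin and poly(A) RNA 0%, 2.99% and 66.7%.

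Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors (RLE) within edgeR, total counts as library sizes, leaving out mitochondrial genes and genes above 1% of any library, no filter, a filter at 1 CPM, a test against a fold of 1.5, leaving out each library, a replicate block, a joint fit of the 8 poly(A) libraries, other set tests, other rankings and exonic length. Alternatives added after seeing the data were a GC correction (offsets from a loess of each library on GC content, span 0.3), restriction of the chromatin comparison to the 13569 genes of at least 1 CPM in poly(A) RNA, both together, thinning of the siCtrl chromatin counts to the siPADI2 depth, and leaving out genes whose 3′ UTR holds either of a pair of 7-mers. Those 7-mers came from a scan, also added after seeing the data, of all 3′ UTR words of length 7 held by at least 30 genes of at least 50 bases of 3′ UTR and an average log2 CPM of at least 2. Fold changes were limited to ±3 in that scan. Scans and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the main comparisons. The values of some list members are not reported here.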

Results

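RNA was sequenced from T47D-MTVL breast cancer cells in 12 libraries, 2 per group. Poly(A) RNA was taken from cells transfected with a control siRNA (siCtrl) or with an siRNA against PADI2 (siPADI2), and from cells labelled as expressing wild-type RNA polymerase II (RNAP2) or its R1810A form, both resistant to alpha-amanitin and kept in the toxin. RNA bound to chromatin was taken after siCtrl and after siPADI2. PADI2 is a peptidylarginine deiminase, an enzyme that turns arginine in proteins into citrulline, and the R1810A form lacks an arginine in the C-terminal domain of the largest RNAP2 subunit. The design asks how loss of the enzyme and loss of its candidate target residue change the RNA of these cells. Total counts of the poly(A) libraries, in units of 1e6, were 44.32 and 132.76 (siCtrl), 112.54 and 127.47 (siPADI2), 128.55 and 130.81 (WT) and 122.25 and 127.19 (R1810A). The chromatin libraries were far smaller, with 7.04 and 6.67 for siCtrl and 2.80 and 2.72 for siPADI2, so changes in chromatin RNA were measured with less precision.

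PADI2 (ENSG00000117115.8, hg19 chromosome 1 from 17393256 to 17445948, minus strand) was the target of the siRNA. In poly(A) RNA it stood at 24.0 and 22.6 CPM in the siCtrl libraries and at 1.83 and 1.88 CPM in the siPADI2 libraries, a 12.5-fold fall (log2 fold change −3.65, SE 0.123, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.11e-25, n = 2). Chromatin RNA held 34.9 and 32.5 CPM after siCtrl and 8.52 and 14.2 CPM after siPADI2 (log2 fold change −1.57, SE 0.245, adjusted p = 9.79e-09). The latter values rest on 24 and 40 PADI2 counts. PADI2 was also low in the libraries labelled R1810A, whose label names no PADI2 siRNA. The WT libraries held 48.9 and 50.7 CPM and those labelled R1810A 3.13 and 2.35 CPM, an 18.2-fold fall (log2 fold change −4.18, SE 0.137, adjusted p = 2.46e-06). The label gives no reason for this fall, so these are called the libraries labelled R1810A throughout, and every direction drawn from them carries that doubt.

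POLR2A (ENSG00000181222.10, hg19 chromosome 17 from 7387685 to 7417933), which encodes the largest RNAP2 subunit, fell from 445 ± 62.0 to 309 ± 3.89 CPM (SD, n = 2) after siPADI2 in poly(A) RNA (log2 fold change −0.53, SE 0.0903, edgeR quasi-likelihood adjusted p = 5.07e-06). It was 521 ± 9.99 CPM in the WT libraries and 362 ± 1.53 CPM in those labelled R1810A (−0.53, SE 0.0680, adjusted p = 3.03e-05). In these 4 libraries its counts may hold transcripts of the transfected cDNA. In chromatin RNA POLR2A did not pass the test (139 ± 4.74 against 99.5 ± 0.375 CPM, log2 fold change −0.48, adjusted p = 0.0903). Its sign turned after GC correction (0.17), which left a positive trend with GC content among expressed genes.

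**Figure D1:**
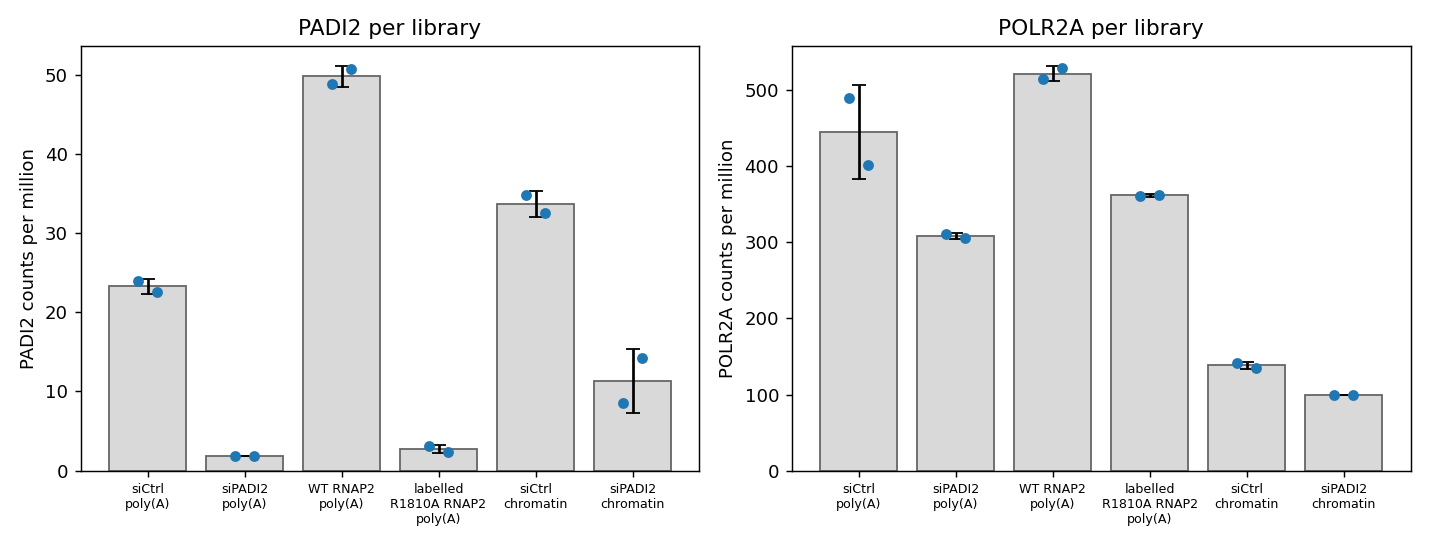
Levels of PADI2 (left) and POLR2A (right) in CPM (y axis) in the 6 groups (x axis), with bars for the mean, error bars for the SD and points for the 2 libraries of each group. PADI2 lies at 1.83 and 1.88 CPM in the siPADI2 poly(A) libraries and at 3.13 and 2.35 CPM in those labelled R1810A, against 22.6 CPM or more in the siCtrl and WT libraries.

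In poly(A) RNA, siPADI2 raised RHBDL3, a rhomboid-family gene, from 1.48 ± 0.165 to 49.5 ± 0.744 CPM (SD, n = 2), and CDC20B, the host gene of the miR-449 microRNAs, from 3.20 ± 0.0758 to 98.7 ± 9.66 CPM. FOXJ1, the transcription factor that drives formation of motile cilia, rose from 2.61 ± 0.414 to 29.8 ± 2.94 CPM, and the membrane glycoprotein gene GPNMB from 96.1 ± 0.180 to 793 ± 53.8 CPM. The opposite held for FMOD, which encodes the matrix proteoglycan fibromodulin (26.4 ± 0.938 to 0.490 ± 0.0327 CPM), SRARP, a regulator of steroid receptors (103 ± 0.589 to 2.08 ± 0.436 CPM), and TNS4, a tensin of focal adhesions (33.3 ± 1.67 to 0.692 ± 0.0742 CPM). SERPINA6, which encodes corticosteroid-binding globulin, fell from 1836 ± 40.5 to 146 ± 7.34 CPM, and CCND1, the G1 cyclin, from 128 ± 6.34 to 21.9 ± 0.860 CPM. ESR1 and PGR, which encode the estrogen and progesterone receptors, fell by 1.60 and 1.66 on the log2 scale.

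The log2 fold changes were 5.02 for RHBDL3 (ENSG00000141314.8, chromosome 17 from 30593195 to 30651680; SE 0.126, edgeR quasi-likelihood adjusted p = 1.42e-29) and 4.94 for CDC20B (ENSG00000164287.8, chromosome 5 from 54408799 to 54469005; SE 0.112, adjusted p = 1.49e-30). The other large increases were SULF1 (3.66), FOXJ1 (3.56), CYP4Z1 (3.51), MOB3B (3.24), PLEKHH2 (3.07) and GPNMB (3.05). FMOD (ENSG00000122176.10, chromosome 1 from 203309756 to 203320617) changed by −5.75 (SE 0.145, adjusted p = 1.47e-29), SRARP (ENSG00000183888.4, chromosome 1 from 16330731 to 16335302) by −5.63 (SE 0.119, adjusted p = 4.92e-29) and TNS4 (ENSG00000131746.8, chromosome 17 from 38632080 to 38657849) by −5.58 (SE 0.137, adjusted p = 8.24e-30). RIPOR3 (−4.67), CPNE7 (−4.03), AZGP1 (−3.97) and SERPINA6 (−3.65) followed. The fixed genes CCND1 (ENSG00000110092.3, chromosome 11 from 69455855 to 69469242; −2.54, SE 0.0884, adjusted p = 5.94e-25), MYC (−1.28, adjusted p = 8.33e-12) and STMN1 (−0.38, adjusted p = 0.000147) fell.

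Of 18720 genes tested in poly(A) RNA after siPADI2, 5395 were higher and 5225 lower (edgeR quasi-likelihood, adjusted p under 0.05), 1461 and 1693 of them by at least 2-fold. With total counts as library sizes all log2 values shifted by a median of 0.18, and 67.0% of the calls were higher in place of 50.8% (7398 higher, 3636 lower). Tested against a fold of 1.5, 1636 genes were higher and 1896 lower. Genes whose 3′ UTR holds both of the 7-mers ATCCACA and TACCATG were lower (median −0.21 over 246 genes, against 0.02 with neither). These words ranked 1 and 2 from the lowest of 16375 scanned in this same comparison, so these medians are no independent test of them. In the scan, which adjusts for 3′ UTR length and GC content, their z scores were −11.8 and −8.90. Both lie past the Bonferroni threshold of 4.67 over all words scanned. With fold changes permuted over genes, 0 words passed it. The medians are not adjusted for 3′ UTR length or GC content. Among the genes named here the 3′ UTRs of RHBDL3, FMOD, AZGP1 and ESR1 hold ATCCACA, that of SRARP TACCATG and that of PGR both.

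Cell cycle genes were lower after siPADI2 in poly(A) RNA. Of 31 measured genes of the G1/S transition and DNA replication 25 fell and 1 rose (median log2 fold change −0.77). Among them were the nucleotide synthesis genes RRM2 (−2.25) and TK1 (−2.05) and the replication licensing gene CDC6 (−1.88). Of 30 genes of G2/M and mitosis 26 fell and 2 rose (27 and 2 adjusted over the list alone), with a median of −0.70 and KIF23 (−1.46), MKI67 (−1.14) and NUSAP1 (−1.05) as examples. Camera gave adjusted p = 8.13e-10 and 1.62e-07 for these lists, and adjusted p = 0.46 for each with an estimated correlation. The 3′ UTRs of 9 of the 31 G1/S genes and of 1 of the 30 G2/M genes hold ATCCACA or TACCATG. Of all 10599 genes scanned in this comparison, 8351 hold neither, so the G1/S share is not far from that of genes at large. For this and the lists that follow, counts adjusted over the list alone equalled those over all genes except where both are given.

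Transcripts of mitochondrial and translation genes fell as well. Of 13 mitochondrially encoded mRNAs 12 fell (13 adjusted over the list alone), with a median of −0.55 and MT-ATP6 at −1.64, MT-ATP8 at −1.48 and MT-ND3 at −1.46 (camera adjusted p = 1.01e-07, adjusted p = 0.46 with an estimated correlation). A joint fit with the R1810A experiment gave adjusted p = 0.0855 for this list. Of 76 cytosolic ribosomal protein genes 37 fell and 3 rose (median −0.19, camera adjusted p = 0.0127, adjusted p = 0.709 with an estimated correlation), including RPS29 (−0.94), RPLP1 (−0.96) and RPL14 (−0.84). Their near-identical copies make these values uncertain. That list lost its call with total counts (adjusted p = 0.0883), after GC correction (0.0517), with fry (0.143) and without siPADI2 replicate 2 (0.167). Among 51 nuclear-encoded genes of oxidative phosphorylation 21 fell and 6 rose (21 and 5 adjusted over the list alone; median −0.17, or 0.01 with total counts; camera adjusted p = 0.075), with COX7A2 at −1.21, NDUFS5 at −0.76 and NDUFA8 at 0.63. That list passed with no filter (0.0377) and without siCtrl or siPADI2 replicate 1 (0.0376 and 0.0260).

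Hormone response and luminal identity genes fell. Of 30 estrogen response genes 20 fell and 4 rose (median −0.72, camera adjusted p = 2.00e-07, adjusted p = 0.193 with an estimated correlation), including PGR and the carbonic anhydrase gene CA12 (−1.47). Of 15 progestin response genes 10 fell and 2 rose (median −0.32, camera adjusted p = 0.0160, adjusted p = 0.46 with an estimated correlation), with TSC22D3 at −1.42, SLC22A5 at −1.22 and ACSL1 at −1.05. Without genes that hold a 3′ UTR 7-mer this call ended (adjusted p = 0.0589). Of 22 luminal epithelial genes 13 fell and 2 rose (median −0.49, camera adjusted p = 1.01e-07, adjusted p = 0.193 with an estimated correlation), among them the prolactin receptor PRLR (−2.70). Of 9 basal, mesenchymal and immune markers 5 fell and 2 rose (3 adjusted over the list alone; median −0.95, camera adjusted p = 0.219), with FN1 at −1.50, VIM at −0.95 and TWIST1 at 2.45. Both peptidylarginine deiminases measured fell, PADI2 and PADI3 (−1.25), and a list of 2 had no set test.

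Interferon, hypoxia and cholesterol genes were also lower. Of 35 interferon response genes 22 fell and 1 rose (23 and 1 adjusted over the list alone; median −0.56, camera adjusted p = 1.52e-06, adjusted p = 0.54 with an estimated correlation), led by MX2 (−2.17), IFITM3 (−1.62) and IFITM1 (−1.20). Of 24 hypoxia and glycolysis genes 21 fell and 2 rose (median −0.72, camera adjusted p = 1.05e-10, adjusted p = 0.193 with an estimated correlation), including the HIF prolyl hydroxylase EGLN3 (−2.96), PFKFB3 (−1.96) and LDHA (−1.70). Of 23 cholesterol synthesis genes 17 fell and 2 rose (18 and 2 adjusted over the list alone; median −0.60, camera adjusted p = 1.20e-06, adjusted p = 0.46 with an estimated correlation), with ACAT2 at −1.12 and NSDHL at −1.08. Other stress lists went both ways and did not pass camera. They include p53 targets (11 of 23 lower and 5 higher, 7 higher adjusted over the list alone; adjusted p = 0.129; CDKN1A −1.54, FAS −1.73, CCNG1 −2.17). The same holds for immediate early genes (9 of 23 lower, 4 higher; 0.190; DUSP6 −2.95, IER3 −1.83, CCN1 1.51) and for the integrated stress and unfolded protein response (11 of 26 lower, 7 higher; 0.323; PDIA4 −1.80, STC2 −1.25, SLC7A11 1.59). The stress response median was −0.06, or 0.12 with total counts. NF-kB targets did not pass (7 of 13 lower, 3 higher; camera adjusted p = 0.219; BIRC3 −1.04, RELB −1.01, NFKBIA −0.67). Nor did heat shock genes (1 of 14 lower, 5 higher; 0.826; HSPB1 −1.03, HSPD1 0.41, HSPH1 0.35). With fry the p53 (adjusted p = 0.0159), integrated stress (0.0306) and NF-kB (0.0306) lists passed, and the interferon list did not (0.0512).

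Genes of the transcription and splicing machinery did not pass camera after siPADI2 in poly(A) RNA. Of 12 RNAP2 subunits 6 fell and 2 rose (camera adjusted p = 0.353), with POLR2E at −0.56 and POLR2C at 0.49. Of 42 genes of pausing, elongation and control of the C-terminal domain 18 rose and 8 fell (median 0.14, or 0.06 after GC correction; adjusted p = 0.368), with the pausing factor genes NELFCD (−0.71) and SUPT4H1 (−0.65) and the elongation gene LEO1 (−0.57) among those that fell. Of 33 spliceosome genes 18 fell and 4 rose (19 and 4 adjusted over the list alone; median −0.24, adjusted p = 0.0569), including SNRPB (−0.81), PRPF4 (−0.76) and SRSF2 (−0.54). Histone genes, which are uncertain because copies share reads, rose in 8 of 14 cases and fell in 1 (median 0.70, adjusted p = 0.0569; H2BC5 1.58, H2BC15 1.24, H2BC21 −1.41). Poly(A) libraries count only transcripts with a poly(A) tail. Their histone, snRNA and snoRNA values therefore do not stand for all transcripts of these genes. In chromatin RNA, measured without poly(A) selection, histone genes fell in 13 of 16 cases after siPADI2. Hosts of small nucleolar RNAs rose in 9 of 15 cases and fell in 2 (median 0.38, adjusted p = 0.0965; EPB41L4A-AS1 1.02, SNHG1 0.67, GAS5 0.61). None of 3 measured RNAP2-transcribed snRNAs and snoRNAs passed the gene test (adjusted p = 0.826 for the list), RNU4-2 standing at −0.55 (adjusted p = 0.263). With fry the spliceosome (adjusted p = 0.0219) and snoRNA host (0.0160) lists passed, and with no filter camera passed these (0.0242 for each) and the histone list (0.0136). The spliceosome list also passed camera in a joint fit with the R1810A experiment (0.0353) and without siCtrl replicate 2 (0.0443) or siPADI2 replicate 1 (0.0314), and the histone list without siCtrl replicate 1 (0.0282) or siPADI2 replicate 2 (0.0156) and without genes that hold a 3′ UTR 7-mer (0.00581).

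By level and length, the highest expression 10th had a median log2 fold change of −0.18 (camera adjusted p = 2.45e-07, adjusted p = 0.271 with an estimated correlation) and the longest 10th of genes by span 0.22 (adjusted p = 0.00421, and 0.199 with an estimated correlation). With total counts the median of the highest 10th was −0.0017. The lowest expression 10th (0.10) and the shortest 10th (−0.15) did not pass (adjusted p = 0.492 for each). With total counts the shortest 10th passed at a median of 0.03 (adjusted p = 0.0258, test direction down), and by exonic length the longest 10th did not (0.14, adjusted p = 0.0972).

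The libraries labelled R1810A were compared with the WT libraries to ask what loss of the arginine changes in poly(A) RNA. CDC20B rose from 18.4 ± 0.0776 to 288 ± 7.69 CPM (SD, n = 2) and GPNMB from 67.4 ± 1.42 to 438 ± 16.1 CPM in the libraries labelled R1810A. TNS4 fell from 20.7 ± 0.811 to 2.01 ± 0.144 CPM, the C-type lectin gene CLEC3A from 468 ± 3.60 to 70.8 ± 1.55 CPM, and CCND1 from 93.4 ± 1.47 to 30.7 ± 1.03 CPM. PADI2 had the largest fall among the genes named by the fixed rule.

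The log2 fold change was 3.97 for CDC20B (SE 0.0676, edgeR quasi-likelihood adjusted p = 1.47e-12) and 3.07 for RHBDL3 (SE 0.0842, adjusted p = 7.19e-11). TXLNB (2.93), CAPN8 (2.80, adjusted p = 0.0200), SULF1 (2.74), GPNMB (2.70), CRYM (2.67) and DNAJC12 (2.64) were the other large increases. Below PADI2 came TNS4 (−3.36, SE 0.0922, adjusted p = 7.19e-11), CHRD, which encodes the BMP antagonist chordin (−2.97), CLEC3A (ENSG00000166509.6, chromosome 16 from 78056412 to 78100658; −2.72, SE 0.0676, adjusted p = 5.62e-11), SRARP (−2.49), MTPN (−2.36), STC2 (−2.31) and the tight junction gene CLDN8 (−2.30). The fixed genes MYC (−1.49, adjusted p = 1.77e-07), CCND1 (−1.60, adjusted p = 5.93e-10), ESR1 (−1.17, adjusted p = 2.22e-08), SERPINA6 (−0.87, adjusted p = 1.83e-06), STMN1 (−0.46, adjusted p = 4.02e-05) and PGR (−0.39, adjusted p = 0.000421) fell. Of 19202 genes tested, 4348 were higher and 4662 lower in the libraries labelled R1810A, 1058 and 983 by at least 2-fold, and 1064 and 1040 passed a test against a fold of 1.5. The balance depends on the scaling, with 5110 higher and 3901 lower with total counts, 4881 and 4261 without mitochondrial and dominant genes, and 4334 and 3979 after GC correction. CAPN8 lost its call without WT replicate 2 (adjusted p = 0.0997). Genes whose 3′ UTR holds both ATCCACA and TACCATG were lower here too (median −0.25 over 253 genes, against 0.02 with neither).

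Cell cycle genes were lower in the libraries labelled R1810A. Of 31 G1/S and replication genes 30 fell (median −0.76, camera adjusted p = 1.06e-18), including TK1 (−1.54), CDC6 (−1.45) and RRM2 (−1.30). Of 30 G2/M and mitosis genes 28 fell (median −0.65, adjusted p = 1.78e-15), including KIF23 (−0.90), NUSAP1 (−0.87) and CCNF (−0.84). With an estimated correlation the adjusted p was 0.764 for these and for every other list that passed in this comparison. The lowest p of that camera test before adjustment over these lists was 0.108, for the G1/S list. Its estimated correlation of 0.435 rests on few residual degrees of freedom with 4 libraries. Ribosomal protein genes, which are uncertain, went up in 36 of 76 cases and down in 3 (median 0.15, camera adjusted p = 0.00423, adjusted p = 0.764 with an estimated correlation), with RPL27A at 0.34, RPS29 at −0.59 and RPLP1 at −0.47, a call that fry ended (0.0766). Genes of oxidative phosphorylation rose in 10 of 51 cases and fell in 5 (8 and 5 adjusted over the list alone; median 0.09, adjusted p = 0.228; COX7A2 −0.43, SDHD −0.35, NDUFS5 −0.33), and passed with no filter (0.0323). No mitochondrially encoded mRNA passed at an adjusted p under 0.05 (0 of 13, median −0.12, camera adjusted p = 0.892), MT-ND6 having a log2 fold change of −0.42. Deviations of same-numbered libraries correlated at 0.693, though the labels state no pairing. With a replicate block MT-ND6 (−0.41), MT-CO3 (−0.48) and MT-ATP6 (−0.49) passed (edgeR quasi-likelihood adjusted p = 5.53e-25, 5.46e-23 and 1.22e-24). MT-ND6 passed with DESeq2 (adjusted p = 0.00212), with no filter (8.64e-08), after GC correction (0.0344) and without WT replicate 1 (0.0447), and MT-CO3 with no filter (0.00282) and without R1810A replicate 1 (0.0477). Counts adjusted over the list alone again equalled the others except where both are given.

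Estrogen response genes fell in 16 of 29 cases and rose in 5 in the libraries labelled R1810A (median −0.34, camera adjusted p = 2.69e-05, adjusted p = 0.764 with an estimated correlation), with TFF3 at −1.38. Luminal genes fell in 13 of 22 cases and rose in 4 (median −0.43, camera adjusted p = 1.52e-05, adjusted p = 0.764 with an estimated correlation), including PRLR (−1.70) and the receptor tyrosine kinase ERBB3 (−1.31). The progestin response list did not pass (7 of 15 lower, 2 higher; adjusted p = 0.0931; CDC42EP3 −1.49, SLC22A5 −0.99, ELF5 0.73). Nor did the basal, mesenchymal and immune markers (3 of 8 lower, 1 higher; adjusted p = 0.192; FN1 −1.05, ACTA2 −1.20, TWIST1 2.04). With fry the progestin list passed (adjusted p = 0.0449). PADI3 fell by 1.29 with PADI2, the only other deiminase measured.

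Interferon response genes rose in the libraries labelled R1810A in 17 of 32 cases (18 adjusted over the list alone) and fell in 4 (median 0.42, camera adjusted p = 0.00196, adjusted p = 0.764 with an estimated correlation), with ISG20 at 1.4 and MX1 at 1.02. Cholesterol synthesis genes rose in 11 of 23 cases (12 adjusted over the list alone) and fell in 4 (median 0.21, camera adjusted p = 0.0221, adjusted p = 0.764 with an estimated correlation), with SQLE at 0.97 and SC5D at 0.93. The cholesterol call ended without WT replicate 1 (adjusted p = 0.0664). Genes of the integrated stress and unfolded protein response fell in 15 of 26 cases and rose in 1 (median −0.28, camera adjusted p = 6.06e-07, adjusted p = 0.764 with an estimated correlation), led by PSAT1 (−1.64) and PDIA4 (−1.53). Of 23 p53 targets 12 fell and 1 rose (median −0.20, camera adjusted p = 0.00196, adjusted p = 0.764 with an estimated correlation), including CCNG1 (−1.72), FAS (−1.62) and TP53I3 (−0.87). Hypoxia and glycolysis genes (9 of 24 lower, 7 higher; adjusted p = 0.124; NDRG1 −1.66, EGLN3 −1.56, PFKFB3 −1.48) and immediate early genes (14 of 25 lower, 5 higher; 0.149; CCN2 −2.25, KLF4 1.34) did not pass camera. NF-kB targets (4 of 12 lower, 2 higher; 0.291; RELB −1.16, NFKBIA −0.48, NFKB1 −0.39) and heat shock genes (2 of 14 higher; 0.182; HSPH1 0.53, HSP90AA1 0.44) did not pass either. Without WT replicate 1 HSP90AA1 lost its call (adjusted p = 0.114), without R1810A replicate 2 the hypoxia list passed (0.0398), and without R1810A replicate 1 or with no filter the heat shock list (0.0444 and 0.0391). With fry the interferon (adjusted p = 0.121) and cholesterol (0.0766) lists did not pass, and without genes that hold a 3′ UTR 7-mer the hypoxia list did (0.00510).

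Of 33 spliceosome genes 16 fell and 1 rose in the libraries labelled R1810A (17 and 1 adjusted over the list alone; median −0.17, camera adjusted p = 0.0399, adjusted p = 0.764 with an estimated correlation), with PRPF4 at −0.61, SRSF2 at −0.56 and SNRPB at −0.48. That call ended after GC correction (adjusted p = 0.0754), with total counts (0.0984), RLE size factors (0.0548), no mitochondrial or dominant genes (0.0618) or a filter of 1 CPM (0.0853), in the joint fit (0.0682), and without WT replicate 2 (0.0581) or R1810A replicate 1 (0.0700). Histone genes, again uncertain and counted only where transcripts have a poly(A) tail, rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.0447, and 0.764 with an estimated correlation), with H2BC15 at 0.71, H1-2 at 0.59 and H2BC21 at −0.49. The call ended without WT replicate 2 (0.0529) or R1810A replicate 2 (0.0616), with a filter of 1 CPM (0.222) and in a joint fit with the siPADI2 experiment (0.0753). RNAP2 subunits (5 of 12 lower, 1 higher; adjusted p = 0.271; POLR2D −0.42, POLR2L −0.40) and pausing and elongation genes (13 of 42 higher, 11 lower; 0.815; AFF4 −0.84, NELFCD −0.48, TCEA1 −0.42) did not pass camera. The same was true of snoRNA hosts (6 of 15 higher, 1 lower; 0.149; EPB41L4A-AS1 0.77, SNHG8 0.55, SNHG5 0.27), which passed without WT replicate 1 (0.0420) or with no filter (0.0391). Only 2 members of the list of snRNAs and snoRNAs were measured and neither passed the gene test, with RNU4-1 at −0.94 (adjusted p = 0.0739). In a joint fit with the siPADI2 experiment POLR2L lost its call (adjusted p = 0.136).

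Splits by level and length gave small medians in the libraries labelled R1810A. The highest expression 10th stood at −0.06 (camera adjusted p = 0.00462; 0.0056 with total counts and −0.0194 without mitochondrial and dominant genes), the lowest at 0.11 (0.0318), the longest 10th at 0.12 (0.0167) and the shortest at −0.13 (0.536). With an estimated correlation all had adjusted p = 0.817. The lowest 10th lost its call without WT replicate 2 (0.22, adjusted p = 0.0651) and turned to −0.03 without R1810A replicate 1.

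The poly(A) comparisons were set side by side by a plan made before the data were examined, and PADI2 mRNA had fallen in both. Of 18260 genes tested in both, 2771 were higher in both (1223 for independent lists, odds ratio 8.79) and 2966 lower in both (1272, odds ratio 10.2). Opposite calls were fewer than independent lists would share, with 269 genes higher after siPADI2 and lower in the libraries labelled R1810A (1324) and 288 the other way (1175). Across genes, which are not independent replicates, log2 fold changes correlated with Pearson's r = 0.653 and Spearman's rho = 0.599. CDC20B, RHBDL3, SULF1 and GPNMB were among the 8 largest increases in both comparisons, and TNS4, SRARP and PADI2 among the 8 largest decreases.

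**Figure D2:**
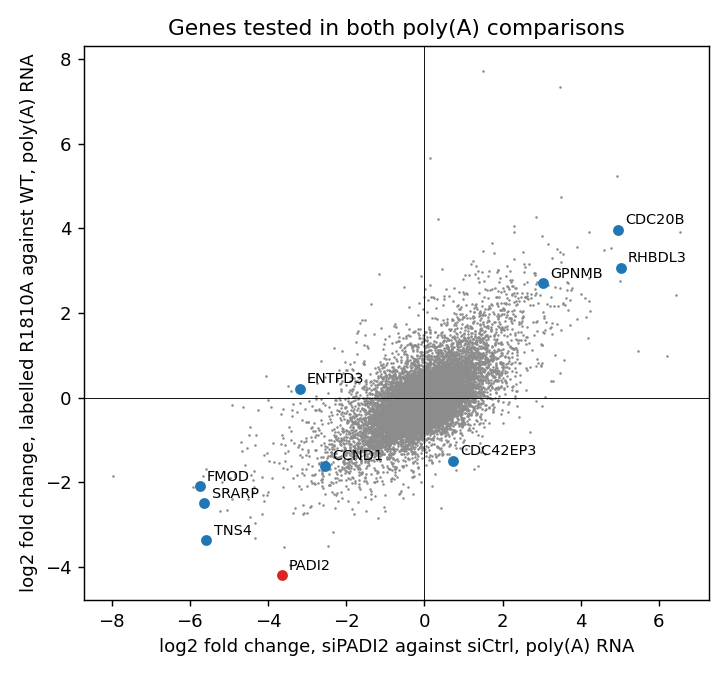
Log2 fold change of each gene after siPADI2 in poly(A) RNA (x axis) against its log2 fold change in the libraries labelled R1810A relative to WT (y axis), 1 point per gene and PADI2 in red. Fold changes rise together (r = 0.653, slope 0.498), with CDC20B at 4.94 and 3.97 and PADI2 at −3.65 and −4.18, and ENTPD3 (−3.18 and 0.22) and CDC42EP3 (0.74 and −1.49) apart from the rest.

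The effects also differed. Tested as an interaction over 19884 genes, 2343 had a higher and 2853 a lower effect of siPADI2 than of the R1810A label (edgeR quasi-likelihood, adjusted p under 0.05). ENTPD3, an ectonucleotidase gene, fell by 3.18 after siPADI2 and stood at 0.22 in the libraries labelled R1810A (difference −3.43, SE 0.103, adjusted p = 2.26e-10). Larger falls after siPADI2 were also found for FMOD (difference −3.69), SERPINA6 (−2.80) and AZGP1 (−2.50). CDC42EP3 rose by 0.74 after siPADI2 and had −1.49 in the libraries labelled R1810A (difference 2.20, SE 0.0963, adjusted p = 6.84e-09), followed by NTN4 (2.06), ZSCAN29 (1.84) and RETREG1 (1.71). Among the fixed genes the effect on PADI2 differed by 0.51 (SE 0.169, adjusted p = 0.0427), on CCND1 by −0.96 (adjusted p = 4.67e-06), on PGR by −1.30 (8.77e-06) and on ESR1 by −0.45 (0.00423), while POLR2A (−0.03, adjusted p = 0.903), MYC (0.19, 0.381) and STMN1 (0.05, 0.726) did not pass. With total counts 3870 genes had a higher and 1822 a lower effect.

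In the siPADI2 chromatin libraries mitochondrial transcripts were higher, and most of the largest falls were in genes silent or nearly silent in poly(A) RNA. MT-CO3 (ENSG00000198938.2, mitochondrial genome from 9207 to 9990), a cytochrome oxidase subunit, rose from 557 ± 5.37 to 2122 ± 370 CPM (SD, n = 2; log2 fold change 1.93, SE 0.381, edgeR quasi-likelihood adjusted p = 8.96e-06). The leukotriene receptor gene CYSLTR1 rose from 11.1 ± 0.116 to 37.2 ± 5.47 CPM (1.74, SE 0.229, adjusted p = 4.90e-12). SPPL2C (ENSG00000185294.5, chromosome 17 from 43922256 to 43924438), an intronless gene of the presenilin-like family, fell from 19.2 ± 5.89 to 0.532 ± 0.25 CPM (−5.11, SE 0.515, adjusted p = 4.46e-20). SERPINA6 fell from 124 ± 11.1 to 45.8 ± 11.1 CPM (−1.44, SE 0.222, adjusted p = 6.19e-09) and MYC from 26.7 ± 1.24 to 11.9 ± 0.737 CPM (−1.16, SE 0.25, adjusted p = 5.17e-05).

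The other large increases were MT-CO1 (1.82), HTN3 (1.76), MT-CO2 (1.76), MT-ND5 (1.73), MT-ATP6 (1.66) and MT-ND3 (1.64), and the other large decreases C3orf22 (−3.13), HOXA6 (−3.11), CD300C (−3.10), RTL1 (−3.08), TMEM86B (−2.97), TMEM204 (−2.94) and LCN1 (−2.89). All 8 of these decreases, SPPL2C included, passed again after GC correction. CCND1 (−0.83, edgeR quasi-likelihood adjusted p = 0.000903) and ESR1 (−0.64, adjusted p = 0.0114) fell, while PGR (−0.16, adjusted p = 0.637) and STMN1 (−0.05, 0.878) did not pass. Without siCtrl replicate 5 MT-CO1, MT-CO2, MT-ND5 and MT-ATP6 lost their calls (adjusted p = 0.0901, 0.0853, 0.129 and 0.0686), MT-ND5 and MT-ATP6 also without siCtrl replicate 1 (0.0736 and 0.0610) and MT-ND5 without siPADI2 replicate 2 (0.0669). ESR1 lost its call with total counts (adjusted p = 0.0501) and without siCtrl replicate 1 (0.0932), siPADI2 replicate 1 (0.0551) or siPADI2 replicate 2 (0.138), and CCND1 without siPADI2 replicate 2 (0.178). Mitochondrial genes took 1.97% ± 0.0638 of the counts in siCtrl and 5.33% ± 1.24 in siPADI2 chromatin libraries.

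Of 33879 genes tested in chromatin RNA, 4140 were higher and 6822 lower (edgeR quasi-likelihood, adjusted p under 0.05), 2382 and 4692 by at least 2-fold. The fold changes followed GC content across genes (Spearman's rho = −0.644), with a median of 0.47 in the lowest and −1.05 in the highest 10th of genes by GC, and correction of this trend left 1959 higher and 2849 lower. After correction rho was 0.304 over expressed and −0.271 over silent genes, so the trend was overcorrected among expressed genes. Here and in the paragraphs that follow, expressed GC-rich genes may have lost calls after GC correction for that reason. With the correction made among genes of at least 1 CPM in poly(A) RNA, 1177 were higher and 1362 lower. With total counts 4156 were higher and 4891 lower. Among the 6735 genes at 0 counts in all 8 poly(A) libraries 1242 were higher and 897 lower, and among the 13434 genes of at least 1 CPM in poly(A) RNA 1005 were higher and 3151 lower. The counts also moved with single libraries, to 1168 higher and 3678 lower without siCtrl replicate 5, 4530 lower and 1482 higher without siPADI2 replicate 2, and to 2347 or 2350 higher without siCtrl or siPADI2 replicate 1. DESeq2 called 537 higher and 3169 lower, and a test against a fold of 1.5 gave 1028 and 3530. Of 93 genes taken by the fixed rule in this comparison, 35 lost the call after GC correction, 2 more with a call turned sign (HSPA1A and SF3A2), as did POLR2A, which had no call (−0.48 and then 0.17), and 14 lost the call with DESeq2. All list calls of this comparison ended with fry.

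**Figure D3:**
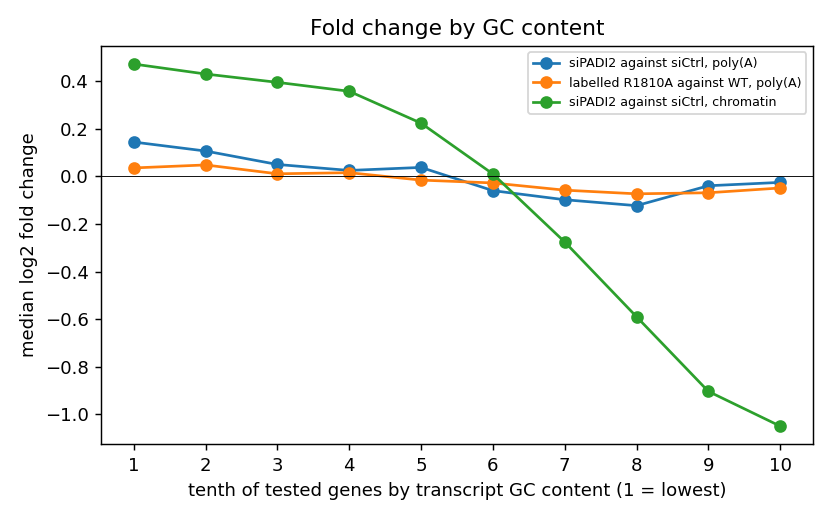
Median log2 fold change (y axis) of genes in each 10th of transcript GC content, from lowest to highest (x axis), with 1 line per comparison. The chromatin comparison runs from 0.47 to −1.05, while siPADI2 in poly(A) RNA runs from 0.14 to −0.03 and the comparison labelled R1810A from 0.04 to −0.05.

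Mitochondrially encoded mRNAs rose in 12 of 13 cases in chromatin RNA (median 1.63, or 1.29 after GC correction; camera adjusted p = 4.72e-11, adjusted p = 0.408 with an estimated correlation). Cytosolic ribosomal protein genes, uncertain as above, fell in 40 of 76 cases (47 adjusted over the list alone; median −0.52, camera adjusted p = 6.51e-08, adjusted p = 0.413 with an estimated correlation), with RPS29 (−1.35), RPS2 (−1.08) and RPL35 (−1.05) as examples. Genes of oxidative phosphorylation fell in 12 of 51 cases (median −0.28, camera adjusted p = 0.00638, adjusted p = 0.455 with an estimated correlation), including COX6A1 (−1.23) and COX7C (−1.20), a call that ended without siPADI2 replicate 2 (0.113). G1/S and replication genes fell in 17 of 31 cases (18 adjusted over the list alone; median −0.59, camera adjusted p = 4.47e-05) and G2/M genes in 12 of 30 (13 adjusted over the list alone; median −0.46, 0.00591), each with adjusted p = 0.408 with an estimated correlation. CDC45 (−2.15), TK1 (−1.71) and MCM2 (−1.33) were examples of the former, and CCNF (−0.87), BIRC5 (−0.87) and MKI67 (−0.84) of the latter. Among genes of at least 1 CPM in poly(A) RNA the G2/M (adjusted p = 0.0847) and oxidative phosphorylation (0.121) lists did not pass, and after GC correction the latter had a median of −0.44. Histone genes, uncertain as above, fell in 13 of 16 cases (median −0.94, camera adjusted p = 5.56e-07, adjusted p = 0.408 with an estimated correlation), with H1-5 at −2.00, H4C3 at −1.38 and H1-4 at −1.37. After GC correction MCM2 (adjusted p = 0.0693), CCNF (0.773), RPS2 (0.523), RPL35 (0.966) and H1-4 (0.164) no longer passed, nor did BIRC5 without siPADI2 replicate 1 (0.0823) or RPS2 without siPADI2 replicate 2 (0.155). Here too, counts adjusted over the list alone equalled the others except where both are given.

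Estrogen response genes fell in 17 of 29 cases and rose in 1 in chromatin RNA (median −0.83, camera adjusted p = 2.60e-05, adjusted p = 0.408 with an estimated correlation), with TFF3 at −1.70, RET at −1.60 and ABCA3 at −1.57. After GC correction the medians were −0.49 for the estrogen, −0.10 for the luminal, −0.38 for the progestin and −0.55 for the deiminase list. Luminal genes fell in 10 of 22 cases (11 adjusted over the list alone; median −0.51, camera adjusted p = 0.00312, adjusted p = 0.55 with an estimated correlation), including KRT19 (−1.64) and PRLR (−1.44). The list lost the call after GC correction (0.0722) or without siPADI2 replicate 2 (0.142). Progestin response genes (5 of 16 lower; adjusted p = 0.0519; HSD11B2 −1.60, STAT5A −1.30, PER1 −1.14) and basal, mesenchymal and immune markers (2 of 17 higher, 2 lower; 0.547; COL1A1 −1.20, TP63 0.71, ZEB2 0.73) did not pass, though the progestin list passed after GC correction (0.0101), with no filter (0.00646), with a filter of 1 CPM (0.0287) and without siCtrl replicate 5 (0.00679) or siPADI2 replicate 1 (0.0357). The 4 deiminase genes measured had a median of −1.20, with PADI3 at −1.21 and PADI1 at −1.18. PADI2, the target of the siRNA, is a member, so the set test of this list is not used. KRT19 (adjusted p = 0.152), HSD11B2 (0.248), STAT5A (0.0680), PER1 (0.716), COL1A1 (0.470), TP63 (0.291), ZEB2 (0.360), PADI3 (0.125) and PADI1 (0.167) no longer passed after GC correction. TP63 also lost its call without siCtrl replicate 1 (0.113) or siPADI2 replicate 2 (0.1), and ZEB2 without siCtrl replicate 1 (0.0979).

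Stress lists in chromatin RNA were mostly lower. Genes of the integrated stress and unfolded protein response fell in 13 of 26 cases (15 adjusted over the list alone; median −0.56, camera adjusted p = 4.79e-05; DDIT3 −1.52, TRIB3 −1.26, DDIT4 −1.22), and hypoxia and glycolysis genes in 11 of 25 (median −0.51, 4.47e-05; SLC2A1 −1.46, PFKFB3 −1.14, ALDOC −1.04). Immediate early genes fell in 10 of 27 (11 adjusted over the list alone; median −0.47, 0.00123; EGR1 −1.45, NR4A1 −1.17), and p53 targets in 7 of 24 (median −0.38, 0.0219; TP53I3 −1.37, CDKN1A −1.10, CCNG1 −1.02). Each of these 4 lists had adjusted p = 0.408 with an estimated correlation. Cholesterol synthesis genes fell in 10 of 24 cases (median −0.30, camera adjusted p = 0.00123; LSS −1.18). NF-kB targets fell in 6 of 19 with 1 higher (median −0.40, 0.0298; TNFAIP2 −1.87, TNFAIP3 −1.61, CSF1 −1.37). Both had adjusted p = 0.413 with an estimated correlation. After GC correction the immediate early (median −0.13, adjusted p = 0.345) and NF-kB (−0.15, 0.472) lists lost their calls, and the hypoxia median was −0.25. The p53 list did not pass among genes of at least 1 CPM in poly(A) RNA (0.148). Without siPADI2 replicate 2 so did the p53 (0.0677) and NF-kB (0.0902) lists, the latter also without siCtrl replicate 1 (0.0553) or 5 (0.112). Interferon response genes went both ways (9 of 34 lower and 5 higher, 11 and 6 adjusted over the list alone; camera adjusted p = 0.933; OASL −1.26, IFIT3 1.05). Their median of −0.05 differed in sign from the test and became 0.06 with total counts and 0.03 after GC correction. Heat shock genes did not pass (3 of 14 lower, 2 adjusted over the list alone; 0.423; BAG3 −0.90, HSPA1A −0.70). HSPA1A turned to 0.21 after GC correction. DDIT4 (adjusted p = 0.173), TRIB3 (0.298), PFKFB3 (0.0582), ALDOC (0.271), EGR1 (0.0764), NR4A1 (0.378), TP53I3 (0.0549), CDKN1A (0.361), LSS (0.198), CSF1 (0.281), IFIT3 (0.0790) and BAG3 (0.668) no longer passed after GC correction. Single libraries ended the calls of EGR1 (without siPADI2 replicate 1, 0.0873), IFIT3 and BAG3 (without siPADI2 replicate 2, 0.117 and 0.0659), OASL (without siCtrl replicate 5, 0.0844) and HSPA1A (without siCtrl replicate 5, 0.225, or siPADI2 replicate 1 or 2, 0.173 and 0.0665).

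RNAP2 subunits fell in 3 of 12 cases in chromatin RNA (median −0.45, camera adjusted p = 0.0323, adjusted p = 0.408 with an estimated correlation; POLR2I −1.78, POLR2L −1.42, POLR2E −0.89). Spliceosome genes fell in 9 of 33 with 1 higher (median −0.31, camera adjusted p = 0.0252, adjusted p = 0.511 with an estimated correlation; SF3A2 −1.01, PRPF31 −0.88, PRPF6 −0.79). The subunit call ended after GC correction (0.472) and both ended without siPADI2 replicate 2 (0.0776 and 0.241), with total counts (0.0535 and 0.0816) and among genes of at least 1 CPM in poly(A) RNA (0.148 and 0.231). The subunit median was −0.24 and SF3A2 turned to 0.04 after GC correction. Pausing and elongation genes did not pass (8 of 42 lower, 2 higher; 0.200), with RPAP2, a phosphatase of the C-terminal domain, at 1.39 and ELL at −1.32. That list passed with no filter (0.0229) and without siCtrl replicate 5 (0.00925) or siPADI2 replicate 1 (0.0417). RNAP2-transcribed snRNAs and snoRNAs, which have near-identical copies, rose in 3 of 15 cases (median 0.77, camera adjusted p = 0.0488, adjusted p = 0.511 with an estimated correlation; RNVU1-7 0.98, RNVU1-18 0.77, RNU1-1 0.71). That call ended with total counts (0.0677), no filter (0.115) or a filter of 1 CPM (0.0572) and without siCtrl replicate 5 (0.571) or siPADI2 replicate 2 (0.113). None of 15 snoRNA hosts passed the gene test (median 0.01, mean −0.02 with the test direction down, −0.20 after GC correction; camera adjusted p = 0.933), with SNHG17 at −0.56. POLR2I (adjusted p = 0.238), POLR2L (0.383), POLR2E (0.998), PRPF31 (0.967), PRPF6 (0.861) and ELL (0.244) no longer passed after GC correction. Single libraries ended the calls of POLR2I (without siCtrl replicate 5, 0.115), POLR2E (without siPADI2 replicate 1, 0.329), PRPF6 (without siPADI2 replicate 2, 0.0791), RNU1-1 (without siCtrl or siPADI2 replicate 1, 0.0940 and 0.0599), RNVU1-18 (without siCtrl replicate 5 or siPADI2 replicate 1, 0.0883 and 0.0592) and RNVU1-7 (without siCtrl replicate 5 or siPADI2 replicate 2, 0.350 and 0.392).

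**Figure D4:**
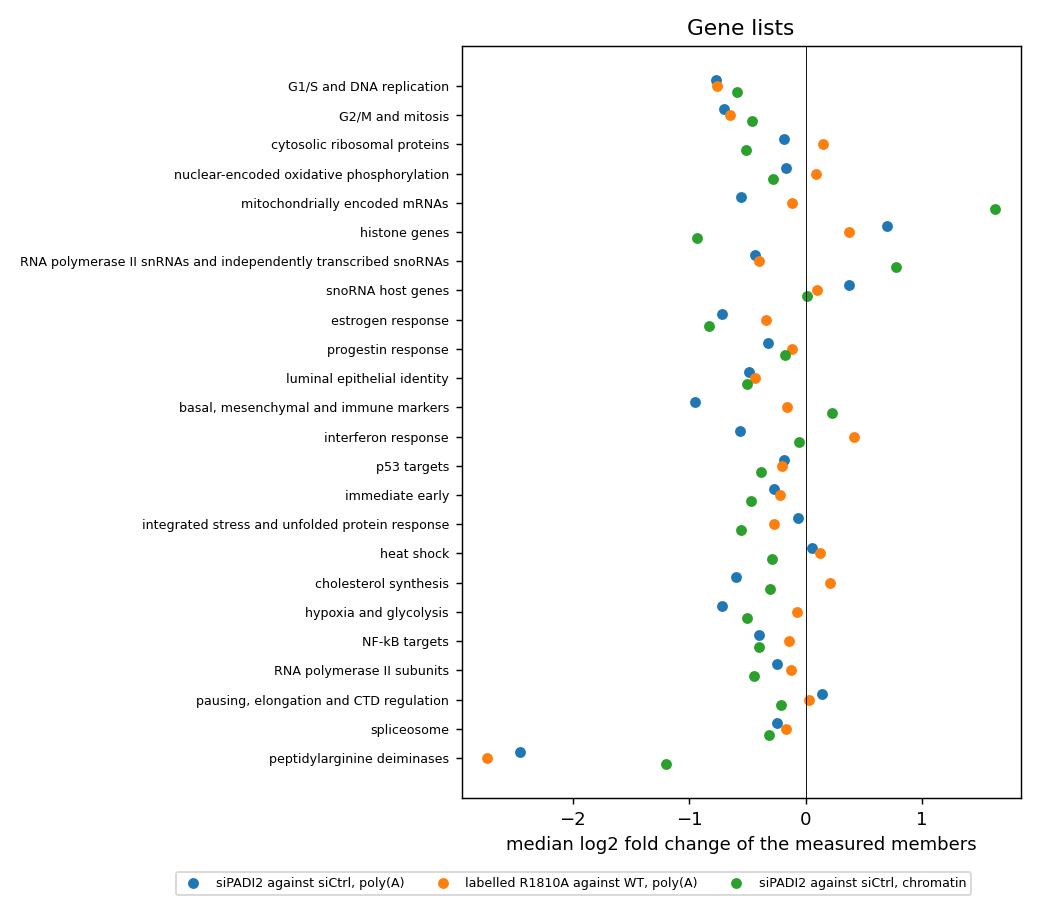
Median log2 fold change (x axis) of the measured members of each of the 24 gene lists (y axis) in the 3 comparisons, 1 point per list and comparison. Mitochondrially encoded mRNAs lie at 1.63 in chromatin RNA and −0.55 in poly(A) RNA after siPADI2, and G1/S genes lie at −0.77, −0.76 and −0.59 in the siPADI2 poly(A), R1810A-labelled and chromatin comparisons.

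By level, the highest expression 10th had a median of −0.19 in chromatin RNA (camera adjusted p = 0.000102, adjusted p = 0.509 with an estimated correlation) and the lowest 10th 0.44 (0.000278, and 0.223 with an estimated correlation). All 3387 genes of that lowest 10th were at 0 counts in the ranking libraries, as were 10785 of the genes tested, so its membership within that tie followed the order of the deposited tables. Both calls ended without siPADI2 replicate 2 (−0.07, adjusted p = 0.192, and 0.17, adjusted p = 0.0523). The longest 10th stood at 0.19 (camera adjusted p = 0.00565) and the shortest at 0.61 (1.98e-06), each with adjusted p = 0.0996 with an estimated correlation. The longest 10th turned to −0.07 after GC correction, and the shortest to −0.37 among genes of at least 1 CPM in poly(A) RNA.

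Calls in chromatin RNA overlapped those in poly(A) RNA more than independent lists would, by a smaller margin than the poly(A) comparisons overlapped each other. Of 17438 genes tested in both after siPADI2, 626 were higher in both (448 for independent lists, Fisher's exact p = 1.70e-24) and 1513 lower in both (1158, p = 1.06e-43). A further 998 were higher in poly(A) and lower in chromatin RNA (1210) and 244 the reverse (429). The correlation across genes was r = 0.174 (rho = 0.196). Against the libraries labelled R1810A, 516 genes were higher in both (368) and 1358 lower in both (1041), with r = 0.145 (rho = 0.162) over 17808 genes.

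The siPADI2 effect itself differed between the RNA fractions for 3592 of 44615 genes, 763 with a higher and 2829 with a lower effect in chromatin RNA (edgeR quasi-likelihood interaction test, adjusted p under 0.05). This excess of lower effects depends on the scaling, with 3002 higher and 3146 lower by RLE size factors and 3511 and 3318 by DESeq2. Differences come from a joint fit of the 8 libraries with its own scaling, so they are not the exact difference of the separate effects printed beside them. SRARP had a log2 fold change of −5.63 in poly(A) and −0.37 in chromatin RNA (difference 5.06, SE 0.432, adjusted p = 1.80e-27), and FMOD −5.75 and −0.79 (difference 4.75, SE 0.490, adjusted p = 1.06e-18). AGXT2 (difference 4.44) and TNS4 (4.12) differed in the same direction. RHBDL3 stood at 5.02 in poly(A) and −0.74 in chromatin RNA (difference −5.94, SE 0.418, adjusted p = 3.35e-41), and FOXJ1 (difference −4.48), the unconventional myosin gene MYO7A (−4.44) and CDC20B (−3.81) also had lower effects in chromatin RNA. CDC20B rose in both fractions (4.94 and 1.32). Of the fixed genes, PADI2 (difference 1.87, SE 0.418, adjusted p = 0.000346), SERPINA6 (2.01, adjusted p = 3.42e-05), CCND1 (1.5, 0.00334) and PGR (1.3, 0.0109) fell less in chromatin RNA, while ESR1 (0.76, adjusted p = 0.284), MYC (−0.09), POLR2A (−0.18) and STMN1 (0.14, adjusted p = 1.00 for these 3) did not pass. For MYC and POLR2A the effects fitted separately differ in the opposite direction. The PGR difference did not pass after GC correction (0.72, adjusted p = 0.499). GC correction took the count of lower effects to 1498, leaving out siPADI2 poly(A) replicate 1 or 2 took it to 1829 or 1783, and leaving out siCtrl poly(A) replicate 2 to 6176. The count of higher effects rose to 2266 without siCtrl chromatin replicate 1 and fell to 420 without siPADI2 poly(A) replicate 1.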

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

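The explanations weighed in this part, and the tests made of them, were chosen after the results were seen. All of the values that follow were singled out because the effect of siPADI2 differed between chromatin and poly(A) RNA in an interaction test. The effect was higher in chromatin RNA for 763 genes and lower for 2829, an imbalance that depends on the scaling (3002 and 3146 with RLE size factors, 3511 and 3318 with DESeq2). The differences come from a joint fit with its own scaling and are not the exact difference of the separate effects given with them. SRARP had a difference of 5.06, from −5.63 in poly(A) to −0.37 in chromatin RNA, where it did not pass (edgeR quasi-likelihood adjusted p = 0.291). AGXT2 had 4.44, from −4.09 to 0.56 (adjusted p = 0.123 in chromatin RNA). FMOD had 4.75, from −5.75 to −0.79 (adjusted p = 0.0558), and TNS4 4.12, from −5.58 to −1.24 (adjusted p = 1.44e-06). RHBDL3 had −5.94, from 5.02 to −0.74 (adjusted p = 0.00778). FOXJ1 had −4.48, from 3.56 to −0.75 (adjusted p = 0.00717), and MYO7A −4.44, from 1.98 to −2.30 (adjusted p = 8.57e-21). CDC20B had −3.81, from 4.94 to 1.32 (adjusted p = 6.94e-09).

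GC-rich genes were lower in the siPADI2 chromatin libraries (Spearman's rho = −0.644 between fold change and GC content), and GC bias of these libraries could account for it. The trend was alike over expressed genes (rho = −0.648) and genes at 0 counts in all poly(A) libraries (−0.595). The latter were tested because they had reads in chromatin RNA, so 0 counts in poly(A) RNA does not show that they were not transcribed. Their rho therefore cannot tell the bias from lower transcription of GC-rich genes. The smaller depth of these libraries is unlikely as the cause, since thinning the siCtrl libraries to the siPADI2 depth left rho at −0.641. In poly(A) RNA rho over expressed genes was −0.0995, too small to tell lower transcription of GC-rich genes from a GC trend of its own. The cause of the trend stays open. How much of the fall in GC-rich genes remains once the trend is removed is open too, because correction left rho at 0.304 over expressed and −0.271 over silent genes.

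Mitochondrial mRNAs were higher in the siPADI2 chromatin libraries (median 1.63) and lower in poly(A) RNA, and 3 explanations were tested. The GC trend is unlikely to be the cause, as the median was 1.29 after GC correction with 11 members still higher. Carry-over of cytosolic RNA would raise ribosomal protein mRNAs as well, and their median was −0.52 with 0 higher and 40 lower. More mitochondrial RNA in the cells would raise it in poly(A) RNA, where the median was −0.55 with 12 members lower. Mitochondria sticking to the chromatin pellet in varying amounts remain possible and could not be tested with these libraries.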

How the results depend on the processing

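Of the alternatives below, GC correction, the limit to genes of at least 1 CPM in poly(A) RNA, both together, thinning and the removal of genes with a 3′ UTR 7-mer were chosen after the data were seen. Direction is compared here only where a gene or list passed in at least 1 of the settings compared, for a list as the test direction. Log2 fold changes of the genes named after siPADI2 in poly(A) RNA kept their side of the threshold, and their direction where they passed, in all 1202 combinations of gene and alternative, in the libraries labelled R1810A in 1158 (17 newly passed, 3 lost the call) and in chromatin RNA in 1141 (5 newly passed, 108 lost the call, 4 reversed). Values that pass in neither setting can turn sign within the kept combinations, as POLR2A did in chromatin RNA after GC correction (−0.48 and then 0.1719). PADI2 kept its call throughout the 3 comparisons, as did all 120 combinations for the genes picked by smallest p in each difference of effects. The fixed genes are not in that count, and PGR lost its call in the difference between fractions after GC correction (0.72, edgeR quasi-likelihood adjusted p = 0.499). Lists, by the same rule, were kept in 305 combinations after siPADI2 in poly(A) RNA (17 calls lost, 21 gained), in 293 in the libraries labelled R1810A (28 lost, 8 gained) and in 279 in chromatin RNA (68 lost, 8 gained). With total counts after siPADI2 in poly(A) RNA the medians of the stress response (−0.06 to 0.12) and oxidative phosphorylation (−0.17 to 0.01) lists turned sign with no call. Thinning the siCtrl chromatin libraries to the siPADI2 depth left 3061 genes higher and 5049 lower and ended the calls of the NF-kB (0.114), RNAP2 subunit (0.0774) and spliceosome (0.105) lists. Without 1 library of a group, the lone library left is assumed to vary like the other groups. Unless a reason is given, the cause of a change named here was not tested.

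The libraries of a group share only a replicate number with those of its control, so a replicate block is given as a check. With 4 libraries it leaves few residual degrees of freedom, so its p-values rest largely on spread borrowed from other genes. It called 5830 genes higher and 5683 lower after siPADI2 in poly(A) RNA and 5975 and 6607 in the libraries labelled R1810A, and 3684 higher and 4080 lower in the difference between these effects. Deviations from the group mean correlated at 0.204 in the first and 0.693 in the second comparison. The lowest expression 10th in the libraries labelled R1810A did not pass with the block (0.11, adjusted p = 0.0952), nor did the histone list (0.0921), while MT-ND6, MT-CO3, MT-ATP6 and RNU4-1 passed there (5.53e-25, 5.46e-23, 1.22e-24 and 0.0212). After siPADI2 in poly(A) RNA the oxidative phosphorylation (0.0133), histone (0.0354), snoRNA host (0.0483) and spliceosome (0.00589) lists passed with the block. No paired analysis was possible for chromatin RNA, or for its difference from poly(A) RNA, because the siCtrl and siPADI2 chromatin libraries share only the number 1.

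A test against a fold of 1.5 asks for larger effects and called 1636 genes higher and 1896 lower after siPADI2 in poly(A) RNA, 1064 and 1040 in the libraries labelled R1810A and 1028 and 3530 in chromatin RNA. With an estimated correlation between genes, which rests on few residual degrees of freedom with 4 libraries, no 10th of expression or length passed. After siPADI2 in poly(A) RNA the values were −0.18 (highest expression, adjusted p = 0.271) and 0.22 (longest, 0.199), in the libraries labelled R1810A −0.0573, 0.11 and 0.12 (highest, lowest and longest, 0.817), and in chromatin RNA −0.19 (highest, 0.509), 0.44 (lowest, 0.223), 0.19 and 0.61 (longest and shortest, 0.0996).

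After siPADI2 in poly(A) RNA the longest 10th by exonic length had 0.14 (adjusted p = 0.0972), and the shortest passed with total counts at 0.0322, opposite in sign to its test direction. In the libraries labelled R1810A the lowest expression 10th lost its call with RLE size factors (0.13), total counts (0.17), no mitochondrial or dominant genes (0.13), no filter (−0.008), no genes with a 3′ UTR 7-mer (0.13), GC correction (0.16) and ranking by the compared libraries (−0.0268). The negative medians had a test direction up. The median of the highest 10th turned to 0.0056 with total counts. This 10th lost its call when ranked by the compared libraries (−0.0397) and the longest by exonic length (−0.0025). Leaving out each library in turn, the longest 10th ranged from 0.0836 to 0.16 (not passing without WT replicate 1), the lowest from −0.0335 to 0.45 (not passing without WT replicate 2 or R1810A replicate 1) and the highest from −0.0945 to −0.0154 (not passing without R1810A replicate 1).

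In chromatin RNA 537 genes were higher and 3169 lower with DESeq2, 1959 and 2849 after GC correction, 1028 and 3175 among genes of at least 1 CPM in poly(A) RNA, where fewer genes are tested, and 1177 and 1362 with both. Leaving out each library in turn gave 1168 to 2350 higher and 3678 to 5641 lower, with fewer samples in each fit. The longest 10th did not pass with no filter (0.0939), by exonic length (0.065), after GC correction, where it reversed (−0.0683), or with that and at least 1 CPM (0.0615). The shortest 10th reversed among genes of at least 1 CPM (−0.37) and did not pass with both (0.0391). Ranked by the compared libraries the highest and lowest 10ths did not pass (−0.0315 and 0.15), and over the leave-outs they ranged from −0.33 to −0.0744 and from 0.17 to 0.56, not passing without siPADI2 chromatin replicate 2. HSPA1A and SF3A2 reversed after GC correction (0.21 and 0.0433) and with at least 1 CPM as well (0.0568 and 0.0064). The rotation test fry ended all list calls of this comparison.

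The difference between the poly(A) effects moved to 3870 higher and 1822 lower with total counts. In the difference between fractions the higher count was 3511 with DESeq2, 3002 with RLE size factors, 1666 with total counts and 472 among genes of at least 1 CPM, and the lower count 1498 after GC correction. Over the leave-outs they ranged from 420 to 2266 and from 1783 to 6176. With DESeq2 159 genes were higher after siPADI2 and lower in the libraries labelled R1810A. The chromatin calls shared with siPADI2 in poly(A) RNA were 100 (both higher), 755 (both lower), 476 (higher then lower in chromatin) and 49 (the reverse) with DESeq2, and 385, 942 and 355 for the first 3 after GC correction, with 788 both lower with total counts and 156 of the last kind with a filter of 1 CPM. Those shared with the libraries labelled R1810A were 91, 683, 343 and 28 with DESeq2, 292, 755, 250 and 150 after GC correction, 826 both lower with total counts and 143 of the last kind with a filter of 1 CPM. Fewer chromatin genes were called after GC correction, so smaller counts do not mean weaker overlap. The odds ratio of both lower went from 1.70 to 2.77 with siPADI2 and from 1.65 to 2.87 with the libraries labelled R1810A. That of both higher went from 1.78 to 1.32 and from 1.68 to 1.19.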

Other observations

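The list of motile cilium genes, the 7-mer search and the tests of explanations in this part were chosen after the results were seen. Genes of motile cilia, a programme known from airway and oviduct epithelium, rose together in poly(A) RNA. Of 38 measured genes of a list of 44, 32 rose and 2 fell after siPADI2 (33 higher adjusted over the list alone; median log2 fold change 1.15; camera p = 5.53e-15, and p = 0.0728 with an estimated correlation). In the libraries labelled R1810A 34 rose and none fell (median 1.58, camera p = 1.59e-41, and p = 0.0380 with an estimated correlation). At the preset correlation, and without the members already seen among the largest changes, the camera p was 1.28e-08 and 3.63e-23. The list was still written after these results and the remaining members come from the same libraries, so these values are no independent test. FOXJ1, the regulator of the ciliary programme, had log2 fold changes of 3.56 and 2.23 in these comparisons, MCIDAS, which drives multiciliated cell fate, 2.31 and 1.48, and CCNO, needed to amplify centrioles, 1.99 and 1.67. Structural genes followed, with TEKT1 at 2.82 and 2.95, ARMC3 at 3.04 and 2.02, CFAP52 at 2.86 and 2.46, HYDIN at 1.60 and 1.79 and RSPH1 at 1.54 and 1.42, while DNAH5 stood at −0.33 and 1.27 and SPEF2 at −0.55 and −0.06. CDC20B, the host of the miR-449 microRNAs that act in multiciliated cells, was among the largest increases in both. In chromatin RNA 5 of 44 rose and 9 fell (median 0.25, and −0.03 after GC correction), and the list did not pass camera.

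PADI2 fell 18.2-fold in the libraries labelled R1810A, and genes moved there much as after siPADI2 (r = 0.653). A candidate explanation is that these libraries hold RNA of cells that received the PADI2 siRNA. Of all 7-mers in 3′ UTRs, ATCCACA went with the lowest fold changes both after siPADI2 (z = −11.8) and in the libraries labelled R1810A (z = −11.6), and TACCATG had z = −8.90 and −7.94, whereas neither stood out in chromatin RNA (−1.08 and −1.01). Both lie in the coding sequence of PADI2, whose transcript holds 21.4% of all 7-mers, but z over all 7-mers correlated at 0.655 between the poly(A) comparisons, so a shared response of any origin could carry these along. A shared GC trend is unlikely, as r was 0.654 after GC correction of both. A response to the R1810A polymerase cannot be excluded. Across genes with neither 7-mer r was 0.681, but later changes after the siRNA would give this as well, so the value decides nothing. What these cells received stays open.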
